A study of Mus musculus with 6 samples.

How the data were processed

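Total RNA from 6 brain samples, 3 labelled wild-type sham and 3 labelled Pla2g2e knockout sham, was measured on 1-colour Agilent arrays of design 026655, 1 sample per array. RNA was purified on columns and labelled with Cy3 from a low input, per the labels' protocols. The deposited files hold the intensity of each spot as extracted from the scanned image by Agilent Feature Extraction 12.1.1.1 with the protocol GE1_1200_Jun14 and a grid built on mm9, per the file headers. The processed signal is an intensity on a linear scale that Feature Extraction had background-subtracted and detrended, and very dim spots carry a surrogate value (2368 to 3150 spots per array), per the file headers and their columns. The mean signal and the local background median are the uncorrected intensities of the same spots, as deposited. Genes well under the background therefore have values set by the extraction software, and fold changes of dim genes depend on how the background was treated.

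Groups and replicate numbers were taken from the sample titles. The replicate numbers were not used as pairs. The slide of each array was taken from the header of its file. In each pair of arrays 0% of the probes held identical values. The 1377 control spots were left out. Spots that the extraction software marked as non-uniform or as population outliers were left out (68 to 530 non-control spots per array). The log2 of the processed signal was taken, and each array's 75th percentile over non-control probes was subtracted. Spots of the same probe were averaged on the log2 scale. A probe was tested when its spots were well above background on every array of at least 1 group and each group had at least 2 values, which kept 31954 of 39429 probes. Where a gene had several tested probes (6256 genes), the probe with the highest mean over all arrays stood for the gene. Where a group was not well above background on any array, the fold was taken against the lowest signal counted as well above background. Where the group's own signal was higher, that signal was used. Such a fold is at most the plain estimate and is not a strict bound.

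Gene names in the files are those of the array design. RefSeq accessions in the files were matched to the names of the GRCm38.p6 annotation table, which renamed or kept 29510 probes, and 2030 probes had no gene name. Coordinates are those of the files (mm9). No gene annotation of mm9 was used here, so the exon or untranslated region under each probe is not given.

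Knockout and wild type were compared gene by gene with limma 3.58.1 (lmFit and eBayes with the default prior) in R 4.3.3, with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over 22578 genes at a threshold of 0.05. All tests were two-sided. Rank or permutation tests of a single gene were not used, since 3 samples against 3 cannot give an exact p under 0.1. Gene lists were tested with limma's camera at a preset correlation of 0.01, with camera at a correlation estimated per list and with fry, each adjusted over the 32 lists with at least 3 tested genes. These set tests used only genes with a value on all 6 arrays, whereas medians and counts of members used all measured genes. Some lists were therefore tested on fewer genes, such as 22 of 24 striatum markers and 46 of 47 neighbours of Pla2g2e. Within a list, p-values were also adjusted over the list alone. The unadjusted p-values, the counts of genes with non-overlapping groups and the neighbourhood counts are given as descriptions.

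The 32 lists were written before the data were examined, from general knowledge and not from these samples. They cover the phospholipase A2 family, neighbours of Pla2g2e on chromosome 4, eicosanoid and polyunsaturated fatty acid genes, peptidylarginine deiminases, lysophospholipid genes, neurotrophic and axon regeneration genes and immediate early genes. Further lists cover inflammatory mediators, interferon response, reactive astrocytes, heat shock and unfolded protein response, glucocorticoid response, circadian clock, and cholesterol and fatty acid synthesis. Markers cover microglia, astrocytes, oligodendrocytes and their precursors, neurons, neocortex projection neurons, striatum, thalamus with habenula and hypothalamus, hippocampus, choroid plexus, endothelium, pericytes, meninges, red blood cells, blood leukocytes and border macrophages. C57BL/6 substrain genes and sex chromosome genes complete them. Some genes belong to 2 or more lists, such as Per1, Glul, Jun, Bdnf and Padi6.

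The genes named in the text follow a rule that was also fixed before the data were examined. It takes Pla2g2e and, in each direction, the 12 genes with the largest difference among those past the threshold with non-overlapping groups. Places left free are filled by smallest unadjusted p among genes with non-overlapping groups and a log2 difference of at least 0.58. Since 0 genes passed, all 12 places in each direction were filled that way, and unnamed or predicted genes were passed over (17 in the higher and 13 in the lower direction). From each list the rule takes up to 4 members, first those past the threshold and then those with the highest mean signal. Genes named outside the rule are said to be so. Some genes that the rule takes are not reported here.

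The test was checked on simulated data, in which 200 of 22304 genes were changed in 20 simulated sets of 3 against 3 arrays with the spread of the real genes. It recovered 70.2% of genes changed by 1 on the log2 scale, 89.9% of those changed by 2 and 95.6% of those changed by 3, with 9.2 false calls per set. In 20 simulated sets of 32 lists, a list shifted by 0.4 was called in 20 sets with the preset and in 17 with the estimated correlation, and 0.05 other lists were called per set. Genes were simulated independently of each other, so these rates do not hold for lists whose members vary together. In the data the estimated correlation was 0.37 for immediate early genes, 0.76 for meninges and fibroblast markers and 0.92 for striatum markers.

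Alternatives fixed before the data were examined were quantile normalization, median centring, the percentile over probes detected on all arrays, normexp with an offset of 50 on the mean and background signals followed by quantile normalization, no filter and a stricter filter on dim probes, and the mean of all probes of a gene. Others were a trended robust prior, the slide as a fixed block, as a random block or restricted to the slide with both genotypes, a replicate block, each array left out in turn, other thresholds, counting probes, and the other set tests. Keeping the spots marked as outliers was added after seeing the data.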

Results

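Gene expression was measured in 6 samples of brain tissue from male mice on the C57BL/6N background, 3 labelled wild-type and 3 labelled as lacking Pla2g2e. Pla2g2e encodes a secreted phospholipase A2, an enzyme that releases fatty acids and lysophospholipids from phospholipids. Titles and descriptions call all 6 samples sham-operated, although the treatment text attached to each of them describes a transient occlusion of the middle cerebral artery. Groups here follow the titles, and no sample titled as ischemic was analysed here. The labels do not settle which text is right, so ischemia in these samples is not excluded. Total RNA was labelled with Cy3 and each sample was hybridised to its own 1-colour Agilent array. The labels do not say that the samples came from separate animals, so p-values measure only the spread between these samples, which may be technical.

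Each array held 43020 non-control spots for 39429 probes. Between 35288 spots (82.0%, wild-type 2) and 36676 spots (85.3%, knockout 2) were well above background, and 0 spots were saturated. The 399 probes printed 10 times on each array had a median coefficient of variation between 3.89% and 4.41%. Wild-type 1, 2 and 3 and knockout 1 shared 1 slide, and knockout 2 and 3 were on a second slide. Knockout 2 and 3 carried 243 and 423 non-uniform spots, against at most 2 on each array of the first slide. Correlations of log2 signals over probes ranged from 0.993 to 0.998 within groups and from 0.992 to 0.996 between groups. On the first principal component, with 42.1% of the variance, wild-type 3 lay at -45.5, wild-type 1 and 2 at -16.6 and -0.87, and knockout 1, 2 and 3 at 10.4, 26.7 and 25.8. The number of arrays limits the precision of every value below.

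The deleted gene was examined first. Pla2g2e had 2 probes on chromosome 4 of mm9, the build named in the file headers, and both were dim. The probe at 138438659 to 138438718 read -7.01 ± 0.30 in wild type and -7.59 ± 0.46 in knockout (log2 signal relative to the array's 75th percentile, SD, n = 3 each), and was well above background on all 6 arrays. Knockout 1 read -7.07, inside the wild-type range of -7.26 to -6.67, while knockout 2 and 3 read -7.87 and -7.83. The difference of -0.59 ± 0.26 (SE) did not pass limma's test with Benjamini-Hochberg adjustment (adjusted p = 0.429). On the slide that holds both genotypes it was -0.06, and without knockout 1 it was -0.85. The probe at 138438368 to 138438427 read -8.74 ± 0.35 in wild type, above background on 2 of 3 arrays, and -8.42 ± 0.03 in knockout, above background on all 3. The 2 probes differed in sign, with 0.33 ± 0.18 (SE) for the second one, whose groups did not overlap. The labels do not say which part of the gene was deleted, so neither probe checks the genotype labels.

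**Figure D1:**
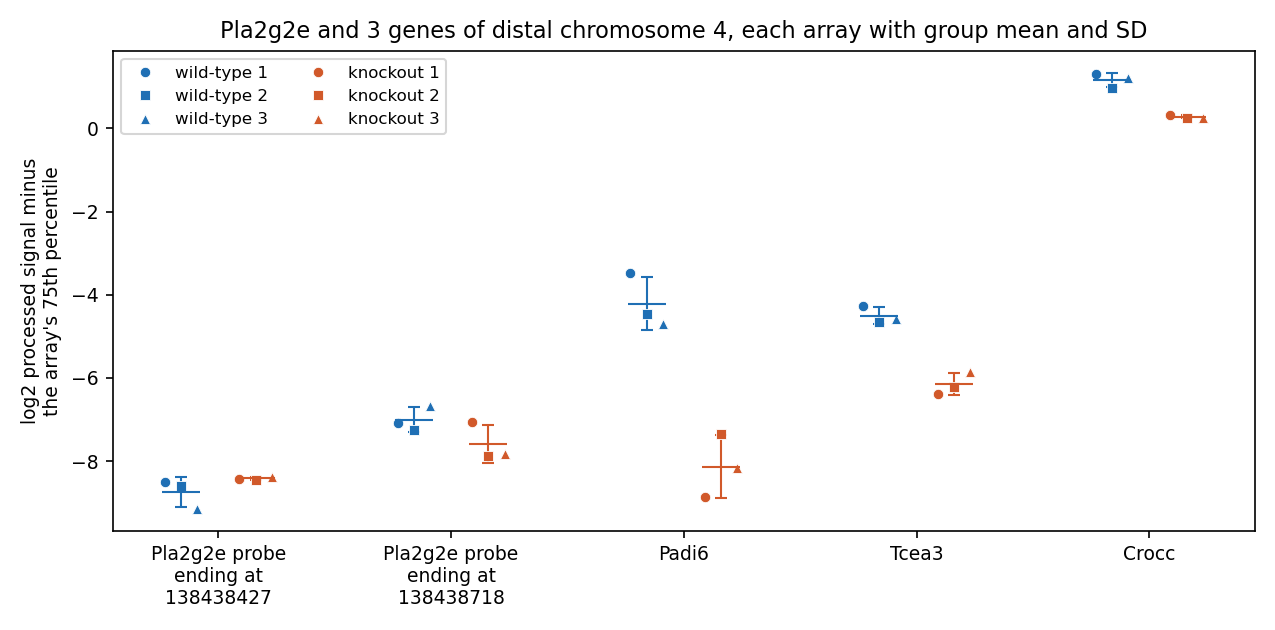
Log2 processed signal minus the array's 75th percentile for both Pla2g2e probes and for Padi6, Tcea3 and Crocc, with 1 point per array and the group mean and SD over 3 arrays as a bar. The Pla2g2e groups overlap at the probe ending at 138438718 (knockout 1 at -7.07), whereas the groups of the other 3 genes do not overlap. At the probe ending at 138438427 they do not overlap either, with knockout higher (-8.44 to -8.38, against -9.15 to -8.50 in wild type).

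The comparison between knockout and wild type asked which genes differ in brain labelled as sham-operated when Pla2g2e is lacking. Among the genes named by smallest unadjusted p, the largest difference was in Padi6, a peptidylarginine deiminase best known from oocytes, whose probe lies at 140283271 to 140283330 on chromosome 4. It read -4.21 ± 0.65 in wild type and -8.13 ± 0.76 in knockout (SD, n = 3 each), 15.1-fold lower, with 2 of 3 knockout arrays well above background. That fold depends on the processing, since the log2 difference was -3.92 here and -1.31 after normexp. The normexp setting adds an offset of 50, which shrinks dim differences by itself and was not separated from the background correction. As lists, immediate early genes were higher in knockout by a median of 0.39 (log2), and markers of meninges and fibroblasts were lower by a median difference of -0.45, both called by camera with its preset correlation but not with an estimated one (adjusted p = 0.717 each). No single gene reached adjusted p under 0.05.

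Of 22578 genes tested, 0 passed limma's test with Benjamini-Hochberg adjustment, and the smallest adjusted p was 0.191. At an unadjusted p under 0.05 there were 2806 genes, where chance gives 1128.9, of which 694 were higher and 2112 lower in knockout. Lower genes made up 75.3% of these under the main scaling, 45.0% under quantile normalization, 40.0% after normexp correction and 24.6% after median centring, which moved the median of all genes from -0.01 to 0.13. Medians of gene lists given below after median centring carry the same shift of all genes. In 4481 genes (19.8%) the 3 knockout values lay all above or all below the 3 wild-type values, where chance gives 10%. With the slide as a fixed block, 1259 genes had an unadjusted p under 0.05, 977 within the slide that holds both genotypes, and 3190 with the slide as a random block (estimated correlation within slides -0.06). Without knockout 1, when each genotype lies on its own slide, 60 genes passed (47 higher, 13 lower), with a median signal at the 6.07th percentile of all genes and 12 olfactory receptors among them.

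None of the genes named next passed the threshold over all genes, and they were taken by smallest unadjusted p among genes with non-overlapping groups. Among the lower ones, Tcea3, a transcription elongation factor (chromosome 4, 135810420 to 135810479), read -4.51 ± 0.20 in wild type and -6.15 ± 0.26 in knockout (SD, n = 3 each), 3.13-fold lower. Crocc, which encodes the ciliary rootlet protein rootletin (chromosome 4, 140572558 to 140572617), read 1.16 ± 0.18 and 0.28 ± 0.03, 1.85-fold lower. Igfbpl1, also on chromosome 4 but far from Pla2g2e (45822379 to 45822438), read -4.74 ± 0.72 and -7.51 ± 0.09, 6.85-fold lower. After normexp the log2 differences of Tcea3 and Igfbpl1 shrank from -1.64 to -0.67 and from -2.78 to -1.03. The adjusted p of Tcea3, Crocc and Igfbpl1 was 0.191 each, as it was for Padi6. Padi6, Tcea3 and Crocc were each tested with 1 probe, so no other probe could be set beside it. The log2 differences of Cd55b, Enpp3, Il21 and B3gnt5 were -0.70, -0.72, -0.72 and -0.72, and -0.26, -0.12, -0.10 and -0.27 after normexp. Smr3a, Psg29, Fancd2os and Olfr1182 were not well above background on any knockout array. They were 3.08-fold, 1.37-fold, 1.78-fold and 1.72-fold lower there, with the dim group set at the lowest signal counted as well above background or at its own signal where higher. For Olfr1182 that fold is the plain estimate. After normexp Smr3a, Psg29, Fancd2os and Olfr1182 differed by -0.27, -0.11, -0.13 and -0.08 (log2). The offset of 50 added there shrinks dim differences by itself, so these values do not test those folds.

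Among the genes higher in knockout, Fosl2, a subunit of the AP-1 transcription factor (chromosome 5, 32460076 to 32460135), read 1.17 ± 0.33 in wild type and 2.03 ± 0.04 in knockout (SD, n = 3 each), 1.81-fold higher, with an adjusted p of 0.235 in limma. Dock4, a guanine nucleotide exchange factor for small GTPases, differed by 0.76 ± 0.14 (SE), or by 0.38 over the mean of its probes, and Dusp4, a phosphatase of MAP kinases, by 0.70 ± 0.11. Tdo2, tryptophan dioxygenase and a marker in the hippocampus list, differed by 0.87 ± 0.14, and by 0.17 after normexp. Asb16, Zar1l, Tnnt2 and Olfr920 differed by 0.59, 0.92, 0.60 and 0.79. Oas1h, Ttc6, Olfr514 and Olfr316 were not well above background on any wild-type array. With the dim group set in the same way, they were 2.66-fold, 1.31-fold, 1.95-fold and 1.70-fold higher in knockout under the main processing. For Olfr316 that fold is the plain estimate. The normexp correction, which adds an offset of 50, shrank the differences of dim genes, from -3.92 to -1.31 for Padi6 and from 0.79 to 0.08 for Olfr920. After it Oas1h, Ttc6, Olfr514 and Olfr316 differed by 0.17, 0.11, 0.13 and 0.05 (log2). These values do not test the folds above, since the offset shrinks dim differences by itself. Without the filter on dim probes the difference of Ttc6 was -0.01.

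The neighbours of Pla2g2e on chromosome 4 were not shifted one way as a list by camera, but fry called them in either direction (adjusted p = 0.00153). Fry compares a list with no other genes, so that call does not set the neighbours apart from the rest. At an unadjusted p under 0.05, 2 of the 47 were higher and 5 lower, where the share over all genes was 12.4%. Groups did not overlap in 5 higher and 7 lower neighbours, where the share over all genes was 19.8%. Of 47 measured neighbours, 0 passed over all genes in limma and 2 were lower adjusted over the list alone, Padi6 and Crocc (adjusted p = 0.00434 each). The brightest members, Camk2n1, Sdhb, Micos10 and Hp1bp3, differed by 0.16, 0.00, 0.08 and 0.07. The list's median was 0.02, its mean -0.13 and its camera direction higher (adjusted p = 0.924). In the peptidylarginine deiminase list, 1 of 5 members was lower adjusted over the list alone (Padi6, adjusted p = 0.000922). Padi2, Padi1 and Padi4 differed by 0.25, -0.25 and -0.09, and camera did not call the list's median of -0.09 (adjusted p = 0.371). In either direction fry called this list (adjusted p = 0.00418), though not after normexp (adjusted p = 0.0609), without knockout 1 (adjusted p = 0.0533), without knockout 3 (adjusted p = 0.0785) or over probes well above background on all arrays (adjusted p = 0.520). Further along the chromosome Spata21, chosen after its values were seen, differed by -1.65 ± 0.26 (SE).

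**Figure D2:**
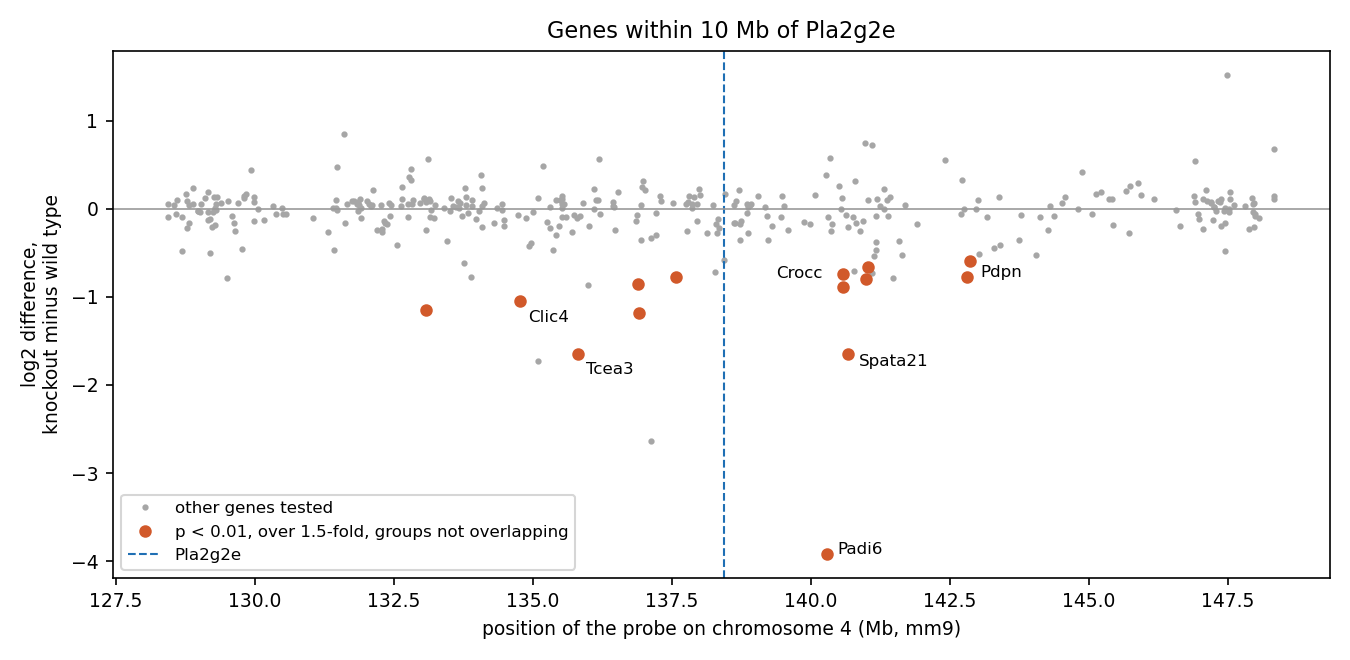
Log2 difference, knockout minus wild type, of genes tested within 10 Mb of Pla2g2e (dashed line), without those not reported here, against the position of its probe on chromosome 4 of mm9, 1 point per gene. Orange points mark 14 genes lower in knockout with an unadjusted p under 0.01, over 1.5-fold and with non-overlapping groups, among which Padi6 lies lowest at -3.92. Other tested probes of Clic4 and Pdpn, not drawn here, differed by 0.01 and 0.23.

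Across the 32 gene lists tested, camera with its preset correlation of 0.01 called 11 lists, 3 higher and 8 lower in knockout, at a Benjamini-Hochberg adjusted p under 0.05. With the correlation estimated per list camera called 0, and fry called 0 in a single direction (smallest adjusted p = 0.318) and 4 in either direction. These 4 were the neighbours of Pla2g2e, the peptidylarginine deiminases, the C57BL/6 substrain genes and the sex chromosome genes, and 0 of them were called with the slide as a fixed block or on the slide that holds both genotypes (adjusted p from 0.0812 to 0.850). At an unadjusted p under 0.05 with an estimated correlation, the hippocampus list had p = 0.0342. Over all genes 0 members of any list passed limma's test. The other 9 splits of the 6 arrays into 3 and 3 gave between 2 and 17 lists.

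**Figure D3:**
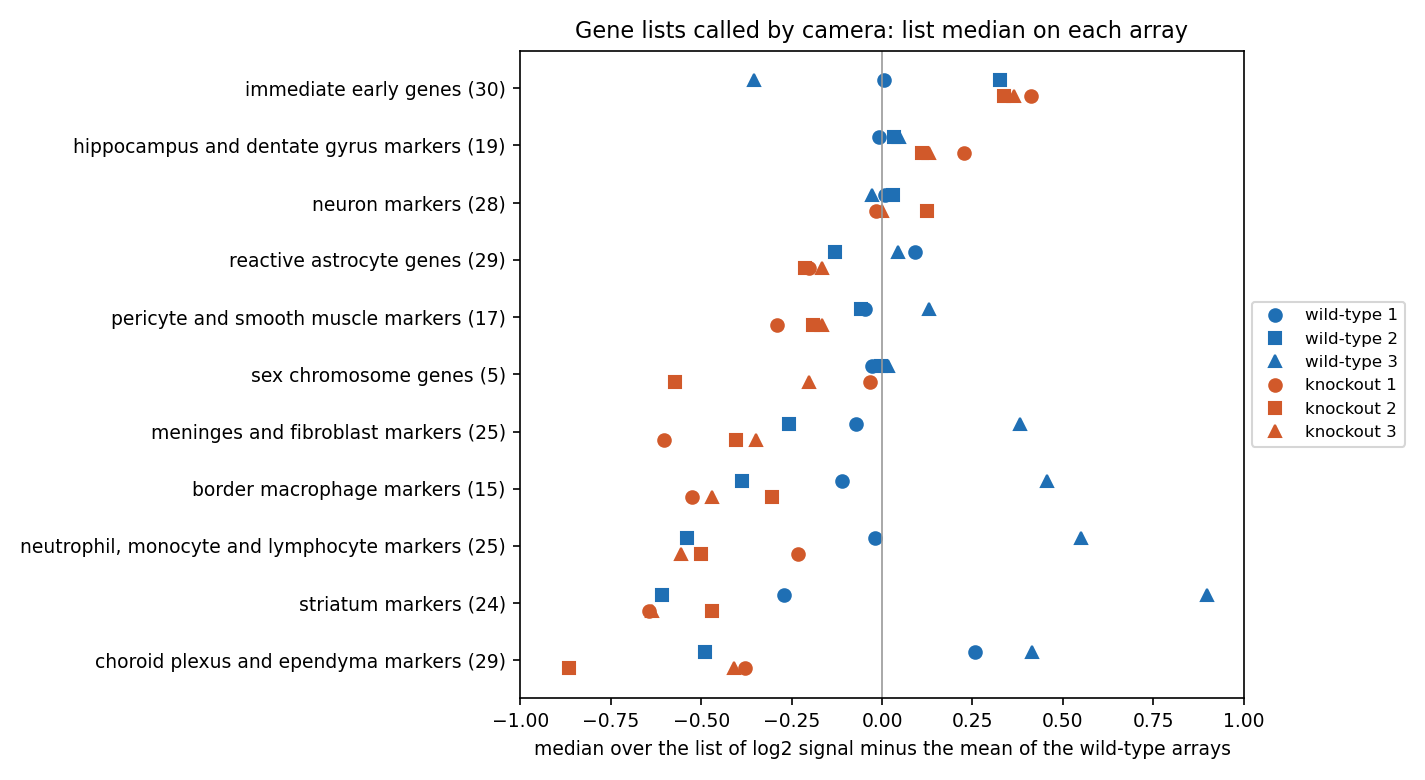
Median over each called list of the log2 signal minus the gene's mean over the wild-type arrays, with 1 point per array and the number of measured genes in brackets. Wild-type 3 (blue triangles) lies apart from the other wild-type arrays in the striatum list (0.90) and the immediate early genes (-0.36), and wild-type 2 lies near the knockout arrays in both (-0.61 and 0.33).

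Immediate early genes, which neurons transcribe within minutes of activity, rose in knockout as a list. Of 30 measured members 27 were higher, the median difference was 0.39, and camera's adjusted p was 7.83e-09 (adjusted p = 0.717 with an estimated correlation). At an unadjusted p under 0.05, 11 members were higher and 1 lower, and 0 passed adjusted over the list alone. Arc, Egr1, Nr4a1 and Per1, the brightest members, differed by 0.39 ± 0.26, 0.36 ± 0.23, 0.72 ± 0.24 and 0.23 ± 0.16 (SE). Without wild-type 3 they differed by 0.09, 0.09, 0.48 and 0.05, without wild-type 2 Arc and Egr1 differed by 0.60 and 0.55, and Per1 differed by 0.37 after median centring and by -0.09 over the mean of its probes. Relative to the wild-type mean, the list's medians were 0.01, 0.33 and -0.36 on wild-type 1, 2 and 3, and 0.41, 0.34 and 0.36 on knockout 1, 2 and 3. Without wild-type 3 the difference was 0.26 (adjusted p = 8.84e-07). With the slide as a block, and within the slide holding both genotypes, it was 0.41. Striatum markers had medians of -0.27, -0.61 and 0.90 on wild-type 1, 2 and 3 and between -0.64 and -0.47 on the knockout arrays.

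Markers of the tissue that covers the brain and of pericytes and smooth muscle were lower as lists. Endothelial markers were not, with 12 higher, 13 lower and a median of -0.06 (camera adjusted p = 0.584). All 25 measured markers of meninges and fibroblasts were lower, with a median of -0.45 (camera adjusted p = 1.79e-08, and adjusted p = 0.717 with an estimated correlation). The brightest were Mgp, Slc13a4, Pcolce and Col1a2, with differences of -0.64 ± 0.35, -0.43 ± 0.20, -0.30 ± 0.21 and -0.50 ± 0.22 (SE), and 0 members passed adjusted over the list alone. Without wild-type 3 these 4 differed by -0.41, -0.21, -0.11 and -0.35, without knockout 1 Col1a2 differed by -0.32, and without wild-type 2 Pcolce differed by -0.47. With the slide as a block Pcolce and Col1a2 differed by -0.46 and -0.87, and after median centring Slc13a4 and Pcolce by -0.28 and -0.15. The list stood at 0.38 on wild-type 3, at -0.07 and -0.26 on wild-type 1 and 2, and between -0.60 and -0.35 on the knockout arrays. Without wild-type 3 its difference was -0.29 (adjusted p = 1.93e-06), and with the slide as a block -0.60. Of 17 markers of pericytes and smooth muscle 16 were lower, with a median of -0.19 (adjusted p = 0.00168, and adjusted p = 0.717 with an estimated correlation). Adjusted over the list alone, 4 fell, namely Acta2, Pdgfrb, Atp13a5 and Notch3, with differences of -0.76, -0.27, -0.44 and -0.28 (adjusted p = 0.0285 each), named after their values were seen. The list's difference was -0.29 with the slide as a block and also without wild-type 2. After median centring, where the median of all genes was 0.13, it was -0.05 and the call was kept (camera adjusted p = 0.00086).

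Lists of striatum, macrophages and blood leukocytes were also called lower, and each call was lost without wild-type 3. All 24 striatum markers were lower, with a median of -0.54 (adjusted p = 0.00193, and adjusted p = 0.717 with an estimated correlation). Penk, Pde1b, Arpp21 and Scn4b differed by -0.47 ± 0.50, -0.25 ± 0.25, -0.11 ± 0.29 and -0.13 ± 0.10 (SE). Without wild-type 3 they differed by 0.10, 0.01, 0.23 and -0.07, so that 3 of these 4 were no longer lower. Over all alternatives the 4 ranged from -0.94 to 0.10, -0.48 to 0.01, -0.32 to 0.23 and -0.27 to 0.01. Without wild-type 3 the list's median was -0.14 (adjusted p = 0.168), without wild-type 2 it was -0.9952 (adjusted p = 1.90e-06), and with the slide as a block it was -0.64. Border macrophage markers, with Stab1, Pf4, H2-Eb1 and H2-Ab1 as the brightest, had a median of -0.49 with 14 of 15 lower (adjusted p = 0.0110, and adjusted p = 0.717 with an estimated correlation). That call was lost without wild-type 3 (-0.15, adjusted p = 0.326) and without knockout 1 (-0.40, adjusted p = 0.0809), and the median was -0.53 with the slide as a block and -0.29 after normexp. Neutrophil, monocyte and lymphocyte markers, led in signal by S100a9, Cd4, S100a8 and Lcn2, had a median of -0.49 with 24 of 25 lower (adjusted p = 0.00562, and adjusted p = 0.717 with an estimated correlation). It was lost without wild-type 3 (-0.14, adjusted p = 0.405) and with the slide as a block (-0.23, adjusted p = 0.221), and the median was -0.91 without wild-type 2 (adjusted p = 1.08e-08) and -0.19 after normexp.

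Choroid plexus and ependyma markers fell, with a median of -0.59 and 26 of 29 lower (adjusted p = 0.00562, and adjusted p = 0.717 with an estimated correlation). Ttr, the abundant transthyretin transcript of choroid plexus, differed by -0.42 ± 0.67, Rarres2 by -0.71 ± 0.32 and Clic6 by -0.76 ± 0.54 (SE). Ttr differed by 0.04 without wild-type 3, by -0.14 without wild-type 1, by -1.17 without wild-type 2, by -0.72 without knockout 1, by -0.27 without knockout 2 and by 0.17 with the slide as a block, and Clic6 by -0.43, -0.44 and -1.40 without wild-type 3, 1 and 2. The call was lost without wild-type 1 (adjusted p = 0.0946), without knockout 2 (adjusted p = 0.0899) and with the slide as a block (-0.38, adjusted p = 0.0973), and the median was -0.38 without wild-type 1 and -0.94 without wild-type 2 (adjusted p = 6.32e-07). Reactive astrocyte genes had a median of -0.16 with 21 of 29 lower (adjusted p = 0.0235, and adjusted p = 0.717 with an estimated correlation). One member, B3gnt5, was lower adjusted over the list alone (adjusted p = 0.0110), while the brightest, Hspb1, H2-T23, S100a10 and Fkbp5, differed by 0.00, 0.16, 0.01 and -0.02. That call was lost without wild-type 1 (adjusted p = 0.129), wild-type 3 (0.112), knockout 1 (0.0567) or knockout 2 (0.0899), and with the slide as a block (-0.20, adjusted p = 0.0973). The median of this list was -0.02 after median centring, -0.09 after normexp and -0.27 without wild-type 2, with the call kept in each (adjusted p from 0.000787 to 0.00414).

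Higher lists besides the immediate early genes were those of hippocampus and of neurons. Hippocampus and dentate gyrus markers had a median of 0.15 with 12 of 19 higher (adjusted p = 0.0110, and adjusted p = 0.717 with an estimated correlation). Tdo2 alone passed adjusted over the list alone (adjusted p = 0.0172), and Dkk3, C1ql3, Wfs1 and Cpne7 differed by 0.36, 0.28, -0.06 and -0.24, with Dkk3 at 0.19 and Cpne7 at 0.17 without wild-type 3. The call was lost without knockout 1 (0.10, adjusted p = 0.103) and after median centring (0.30, adjusted p = 0.178). The median was 0.25 under quantile normalization, 0.10 without the filter on dim probes, 0.03 without wild-type 2 (adjusted p = 0.0477), and 0.23 both without knockout 3 and with the slide as a block. Neuron markers had a median of 0.04 with 21 of 28 higher (adjusted p = 0.0387, and adjusted p = 0.717 with an estimated correlation). Rtn1, Thy1, Syt1 and Snap25 differed by 0.01, 0.05, 0.00 and 0.00, and the call was lost after the normexp correction (adjusted p = 0.390), under quantile normalization, without the filter on dim probes (0.0932), without wild-type 1 (0.0627), wild-type 3 (0.307) or knockout 2 (0.289), and with the slide as a block (-0.02, adjusted p = 0.395). The median of neuron markers was 0.19 after median centring, 0.02 without wild-type 3 and -0.01 without knockout 2.

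The 5 sex chromosome genes had a median of -0.37 (adjusted p = 0.0306, and adjusted p = 0.717 with an estimated correlation). They mix the X-linked Xist, named outside the rule, with the Y-linked Kdm5d, Eif2s3y, Ddx3y and Uty. Xist was dim and read between -10.57 and -7.62, around the lowest signals counted as well above background (-8.93 to -8.78 over the arrays). Kdm5d, a Y-linked histone demethylase, differed by -0.50 ± 0.07 (SE) and passed adjusted over the list alone (adjusted p = 0.00252), with a difference of -0.13 after normexp. Eif2s3y, Ddx3y and Uty differed by -0.37, -0.12 and -0.19, and knockout 2 deviated from the mean of the other 5 arrays by -0.84, -0.59 and -0.57 for them (log2). In either direction fry called the list (adjusted p = 0.00418), though not after quantile normalization (adjusted p = 0.322), median centring (adjusted p = 0.205) or normexp (adjusted p = 0.499), nor without knockout 2 (adjusted p = 0.0556) or knockout 3 (adjusted p = 0.0505). For camera, the list's median was -0.23 after median centring. Without knockout 2 the list's median was -0.12 (adjusted p = 0.287), with the slide as a block -0.03 (adjusted p = 0.588), and the call was lost after normexp (-0.12, adjusted p = 0.0644), over probes well above background on all arrays (adjusted p = 0.0599), and without wild-type 1 (0.0616), wild-type 2 (0.108) or wild-type 3 (0.0797).

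Camera did not call the lists closest to the function of Pla2g2e in the comparison of all 6 arrays. The 26 measured members of the phospholipase A2 family had a median of -0.10 (adjusted p = 0.636), and Pafah1b1, Pla2g7, Plaat3 and Pafah1b3 differed by 0.10, 0.00, -0.09 and 0.26. The 48 genes of eicosanoid and polyunsaturated fatty acid metabolism had a median of -0.13 (adjusted p = 0.232), with Ptgds, Fabp5, Ptges and Ptges3 at -0.14, -0.07, -0.04 and 0.02. The 35 genes of lysophospholipid remodelling and signalling had a median of -0.06 (adjusted p = 0.511), with Enpp2, Lypla2, Plpp3 and Agpat4 at -0.16, 0.15, -0.01 and -0.08. After median centring the medians of these 3 lists were 0.04, 0.02 and 0.08, and without wild-type 3 they were 0.01, -0.06 and -0.02. The 40 neurotrophic and axon regeneration genes had a median of -0.07 (0.07 after median centring), with Tuba1a, Stmn4, Vgf and Stmn2 at -0.09, -0.16, 0.24 and -0.06 (adjusted p = 0.180). This last list was called with the slide as a fixed block (-0.17, adjusted p = 0.0383) and without wild-type 1 (-0.10, adjusted p = 0.0432). In each of these lists 0 members passed adjusted over the list alone.

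Inflammatory mediators and danger signal genes had a median of -0.23 over 38 members (adjusted p = 0.306), with Prdx5, Prdx6, Prdx2 and Hmgb1 at 0.01, -0.15, 0.11 and -0.35. They were called after median centring (-0.09, adjusted p = 0.0274) and without wild-type 2 (-0.29, adjusted p = 0.0125). The median was -0.07 without wild-type 1 (adjusted p = 0.995) and after normexp (adjusted p = 0.204), -0.12 under quantile normalization, and -0.09 with the slide as a block (adjusted p = 0.655). Interferon response genes had a median of -0.01 and a mean of -0.04 over 33 members but a camera direction of higher (adjusted p = 0.777), and Ifi27, Lgals3bp, Stat2 and Igtp differed by 0.01, -0.08, -0.16 and 0.22. Without wild-type 3 the list was called by camera with a median of 0.10 (adjusted p = 0.00187). Its median was -0.17 with the slide as a block, and -0.10 without wild-type 1 and also without wild-type 2. Heat shock and unfolded protein response genes (median 0.05, with Hspa8, Hsp90aa1, Atf4 and Hspa5 at 0.03, -0.01, -0.01 and 0.09) and glucocorticoid response genes (median 0.02, with Mt1, Mt2 and Glul at -0.05, -0.03 and 0.10) had an adjusted p of 0.143 each. The heat shock list was called without wild-type 2 (0.12, adjusted p = 0.000517). The glucocorticoid list was called as higher with the slide as a fixed block (0.04, adjusted p = 0.00573), on the slide that holds both genotypes (adjusted p = 0.00559), without wild-type 1 (0.19, adjusted p = 0.00330) and without knockout 3 (0.06, adjusted p = 0.0105). The circadian clock list had a median of 0.09 (adjusted p = 0.120), with Tef, Cry2 and Dbp at -0.10, 0.11 and -0.23, and was called without wild-type 1 (adjusted p = 0.0224). Cholesterol and fatty acid synthesis genes had a median of -0.06, or 0.08 after median centring (adjusted p = 0.344), with Scd2, Hmgcs1, Acly and Msmo1 at -0.13, -0.07, 0.02 and -0.15, and after normexp their list was called (-0.05, adjusted p = 0.04995). None of these lists held a member that passed adjusted over the list alone.

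Camera did not call the markers of most other cell types in the comparison of all 6 arrays. Microglia markers had a median of 0.00 (adjusted p = 0.463), with Siglech, Itgam, Csf1r and Ctss at -0.12, -0.17, -0.03 and 0.24, and were called without wild-type 3 (0.08, adjusted p = 0.00877). Astrocyte markers had a median of -0.03, a mean of -0.01 and a camera direction of higher (adjusted p = 0.858), with Aldoc, Clu and Ndrg2 at 0.01, -0.05 and -0.04. Oligodendrocyte and myelin markers had a median of -0.27 with 25 of 28 lower (adjusted p = 0.143), with Trf, Apod and Mal at -0.12, -0.36 and -0.33, and oligodendrocyte precursor markers a median of -0.09, or 0.05 after median centring (adjusted p = 0.463), with Cspg5, Gpr17, Ptprz1 and Olig1 at 0.04, -0.26, 0.08 and -0.08. The oligodendrocyte list was called after normexp (-0.28, adjusted p = 0.00366), quantile normalization (-0.28, adjusted p = 0.0105) and median centring (-0.13, adjusted p = 0.00414), without wild-type 3 (-0.52, adjusted p = 9.06e-05) and without knockout 1 (-0.40, adjusted p = 0.0383). Its median was 0.02 without wild-type 2 (adjusted p = 0.416), -0.08 without knockout 2 (adjusted p = 0.971) and -0.01 with the slide as a block (adjusted p = 0.368). The precursor list was called without wild-type 1 (-0.14, adjusted p = 0.0224). Endothelial markers had a median of -0.06, or 0.08 after median centring (adjusted p = 0.584), with Cd34, Egfl7, Slc2a1 and Ly6c1 at 0.29, 0.04, 0.05 and 0.10. Red blood cell genes varied widely between arrays, from -1.20 on knockout 3 to 0.93 on knockout 2, with a median difference of -0.51 (adjusted p = 0.451) and with Hba-a2, Fech and Hba-a1 at -0.69, 0.11 and -0.79. They were called by camera without knockout 2 (-1.11, adjusted p = 0.00534), and their median on the slide that holds both genotypes was -1.12. Without knockout 1 their median was 0.01 (adjusted p = 0.816), without wild-type 1 it was -0.16, and without knockout 3 it was -0.20.

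Neocortex projection neuron markers had a median of 0.03 (adjusted p = 0.344), with Tbr1, Etv1, Neurod2 and Lhx2 at 0.00, 0.48, 0.03 and 0.20. The list of thalamus, habenula and hypothalamus markers had a median of -0.18 (adjusted p = 0.274), with Hap1, Ramp3, Tac2 and Ntng1 at -0.17, 0.08, 0.09 and -0.13, and was called after median centring (-0.03, adjusted p = 0.0104). The C57BL/6 substrain list was written from general knowledge, and whether each member differs between substrains was not checked. Its 11 measured genes had a median of 0.06 and were not called in a single direction by camera (adjusted p = 0.319). In either direction fry called them (adjusted p = 0.00153), though not after normexp (adjusted p = 0.123) or without the filter on dim probes (adjusted p = 0.538), and fry compares a list with no other genes. Cyfip2, Glo1, Nnt and Gabra2 of that list differed by 0.11, 0.06, 0.00 and -0.16. In none of these lists did a member pass adjusted over the list alone.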

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

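The alternative that kept spots marked as outliers was chosen after seeing the data, and the others before. Under limma with Benjamini-Hochberg adjustment, 0 genes passed in the main comparison and under 21 of its 22 alternatives, including adjusted p under 0.1 and counting probes. Leaving out single arrays gave between 0 and 60 genes, with the 60 found without knockout 1, when genotype and slide coincide, so that they cannot be told apart. Genes at an unadjusted p under 0.05 numbered 2806, and 1259 with the slide as a fixed block, 3190 as a random block, 977 within the slide that holds both genotypes, and between 1639 and 3338 with single arrays left out. The fixed block and the single slide rest on 1 knockout array, which by construction leaves fewer arrays for the test. Lower genes were 75.3% of these in the main comparison, and 45.0%, 40.0% and 24.6% under quantile normalization, normexp and median centring. The count of shifted lists was 11 in the main comparison, 0 with an estimated correlation and 0 by fry, and 8 to 13 under the other 19 alternatives. Calls of immediate early genes, meninges and fibroblasts, and pericytes and smooth muscle held under all 19. Over 32 lists and 19 alternatives, 33 of 608 values lost a call and 22 passed the threshold anew. The others stayed on their side of it, 514 in the same direction and 39 uncalled with another direction, and 0 reversed a call. For the named genes 1 of 2803 values passed anew (Fancd2os without knockout 1), and the others stayed uncalled, 2582 in the same direction and 220 with another sign. The difference of Pla2g2e ranged from -0.85 to -0.06 (adjusted p 0.147 to 1.00), with -0.08 after normexp and -0.13 over the mean of its probes.

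Knockout 1 differed from the mean of the other 2 knockout arrays by a median of 0.112 (absolute log2 over genes). This became 0.134 under median centring, 0.0769 after normexp and 0.139 without the filter on dim probes, and the cause was not tested. The same measure was 0.112, 0.136 and 0.152 for wild-type 1, 2 and 3, which share a slide, and 0.104 and 0.0662 for knockout 2 and 3. Over 2-fold from the mean of the other 2 arrays of the group lay 518 genes in knockout 1, 182 and 224 in knockout 2 and 3, and 226, 451 and 647 in wild-type 1, 2 and 3. The measure uses no block, and settings that leave out arrays gave no value for it. The samples of both groups share only a number: deviations of arrays with the same replicate number correlated at -0.02, -0.13 and -0.12, and no array of the 6 correlated best with its own number. The replicate block gave 0 genes (2406 at an unadjusted p under 0.05) and 11 lists, and moved no list across the threshold among those called. Signal over background limits the dim genes, where normexp shrank the differences, though no setting separated its added offset from its background correction.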

Other observations

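The tests of slide, strain DNA and covering tissue for the chromosome 4 genes, and the test of covering tissue for the meninges markers, were chosen after the results were seen, as were the intervals from 1 median per array. Other gene groups held differences that did not pass over all genes or adjusted over the list alone, and their genes were named after their values were seen. Among cholesterol synthesis genes, Lss, Dhcr7 and Mvd were lower by differences of -0.32 ± 0.07, -0.24 ± 0.06 and -0.26 ± 0.08 (SE), each with non-overlapping groups. Gdnf, a neurotrophic factor, differed by -1.59 ± 0.45, and the lysophosphatidic acid receptor Lpar3 by -0.92 ± 0.25. Il6 and Casp1 differed by 0.47 ± 0.10 and 0.54 ± 0.12, and Tnf by -0.54 ± 0.22. Myelin basic protein, Mbp, differed by 0.33 ± 0.09, against the median of -0.27 of its list.

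Genes near Pla2g2e differed more often than genes on other chromosomes at each of 6 nested window widths tried. Odds ratios were 3.75, 5.06, 2.70, 2.21, 1.97 and 1.74 within 2, 5, 10, 15, 20 and 30 Mb. The 95% interval of the first, from 0.989, includes 1. Between 0.409% and 6.99% of windows elsewhere reached the share. The windows share their differing genes, with 14 of 193 genes within 5 Mb, 15 of 375 within 10 Mb and 20 of 766 within 30 Mb. The 6 ratios are therefore not separate results. Beyond 5 Mb the share on chromosome 4 was 1.44%, against 1.52% on other chromosomes. Within 10 Mb, 15 of 375 genes (14 lower) had non-overlapping groups, an unadjusted p under 0.01 and over 1.5-fold, against 321 of 21111 on other chromosomes (1.52%), an odds ratio of 2.698 (95% interval 1.48 to 4.58, Fisher's exact p = 0.000894), and 3.39% of windows elsewhere reached that share. For the slide, 20 genes of the window were chosen without knockout 1 by the same limits, and knockout 1 showed a median of 0.8296 of their difference (quartiles 0.129 and 1.08), against 0.211 over 736 genes of other chromosomes, where chance in the shared wild-type mean alone gives 0.4. Since the lower quartile lies under 0.4, the slide stays open for part of the genes. Base differences under single probes stay open too (median 0.1452 toward the first probe over only 4 other probes). Among these other probes, all of genes named outside the rule, those of Spata21 and Mfap2 differed by -1.31 and -0.30 (first probes -1.65 and -0.74). Those of Clic4 and Pdpn differed by 0.01 and 0.23 (first probes -1.05 and -0.59). More covering tissue in the wild-type samples also stays open. For it the excess of wild-type 3 (0.07032 of the fall in knockout) decides nothing, because the choice of genes favoured a small wild-type spread. DNA from another strain kept around the deleted gene, which may alter expression there, is a hypothesis that cannot be told apart from these, and the labels used here do not name the cells in which the gene was targeted.

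Lower markers of meninges and fibroblasts were the second pattern. The median was -0.2919 without wild-type 3 and -0.6024 on the slide that holds both genotypes, where 1 knockout array was measured. From 1 median per array, the 95% intervals of these differences were -0.69 to 0.16 and -2.25 to 1.01, so that neither 1 wild-type library nor the slide is excluded. Whether more covering tissue was taken with the wild-type samples stays open too and cannot be told apart from an effect of genotype: medians of the meninges, choroid plexus and border macrophage lists lay between -0.59 and -0.45, and that of smooth muscle was -0.1904. In wild-type 3 the meninges markers exceeded the other wild-type arrays by 1.16 of the difference between genotypes (median over the list), so that samples of 1 genotype may differ as much.

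Higher immediate early genes were the third. The median was 0.2586 without wild-type 3 and 0.4111 on the slide that holds both genotypes, with 95% intervals from 1 median per array of -0.15 to 0.65 and -1.28 to 2.11. Wild-type 2 (0.33) lay next to the knockout arrays (0.34 to 0.41), so that neither 1 wild-type library nor the slide is excluded. Striatum markers had medians of 0.90 on wild-type 3, -0.61 on wild-type 2 and -0.64 to -0.47 on the knockout arrays, in the direction opposite to these genes on each of them. Neural activity before death, the part of the brain sampled and genotype all remain possible and were not tested.

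With 6 arrays the 10 splits into 3 and 3 are too few for a share under 0.05. For genes past the adjusted threshold the real count was 0 and the highest other count 0, as all 10 splits gave. For genes at an unadjusted p under 0.05 the real count was 2806 and the highest other 1624, from the split that sets wild-type 1, wild-type 2 and knockout 1 against the rest, and only the real split, 1 of 10, reached the real count. Of the 10 splits, 6 shifted at least 11 lists, and the highest other count was 17.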
